A study of Homo sapiens with 2 samples.

How the data were processed

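Gene expression was measured in ATN-1, an established cell line from adult T-cell leukemia/lymphoma, a T-cell malignancy caused by the retrovirus HTLV-1. Cells from mono-culture gave 1 sample, and cells grown for 3 weeks with human monocyte-derived macrophages gave the other. The macrophages had been removed with magnetic beads against CD14, a monocyte and macrophage surface protein, before RNA was extracted. Groups were taken from the label that says what each sample was cultured with, since the treatment protocol reads the same for both. Total RNA was labelled with Cy3 and hybridised to Agilent 1-colour arrays, and both arrays lay on the same slide and were read in the same scan.

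Per the file headers, the scanner files were written by Agilent Feature Extraction 10.7.1.1, while the submitters' processing notes name version 9.5.1.1. The deposited scanner files hold spot intensities on a linear scale, after background subtraction and detrending within the array by that software, and are not normalized between arrays. Each array held 58717 spots, of which 4259 were controls. The software set non-uniformity or population outlier flags on 328 further spots of the mono-culture array and 329 of the co-culture array, and no spot was saturated. The authors' deposited value table holds linear values of the same probes. Its sorted columns were equal within 0.0207%, both had a median of 11.9, and each correlated with its own scanner values (r = 0.99997 and 0.99996 across probes on the log2 scale), so that its scale and direction are known and its columns share 1 distribution. The tool behind that table is not given in the sources used here. It served as an alternative only.

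Control and outlier spots were left out, log2 intensities of the spots of a probe were averaged, and the array's 75th percentile was subtracted. That percentile was 217 in mono-culture and 189 after co-culture. A probe was kept if the software called it well above background on at least 1 array. This held for 22591 of 50598 probes (44.6%) in mono-culture and 21972 (43.4%) after co-culture, and the lowest signal called well above background was 18.6 and 17.2. A gene took the value of its brightest probe by mean log2 signal. Probes of sex-linked transcripts (237) were left out of every step after scaling. Differences are log2 after co-culture minus log2 in mono-culture throughout. Where a gene was not well above background on 1 array, the fold is a lower bound, "at least", against the higher of that array's lowest signal well above background and the probe's own signal. If the probe's own signal was the higher, that fold is the measured one and not a true lower bound. No probe's level is set against another's.

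Probe names came from accessions matched to a RefSeq gene table of assembly GRCh38 (28173 probes), from its symbols (2618) or its older symbols (620). The name in the array file was kept for 17273 probes, and 1914 had no gene name. Printed coordinates are the probe positions in the array files, build hg19. Exon and UTR annotation of that build was not used here.

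With 1 array per group there are no replicates, so no test, p-value or spread between samples exists, and the number of arrays limits the precision. The errors available are technical. The scanner software's error model gave a median error of 0.21 for a log2 difference. Over the 578 probes with 10 spots that were well above background on both arrays, the difference of single spots had a median SD of 0.088 and a 95th percentile of 0.27 on the log2 scale. A gene counts as dim on an array only if all its probes are. A difference of at least 2-fold served as a size threshold, not as a test. The co-culture array met 9 of 10 quality ranges of the scanner software, with the negative control signal (40.1) outside its range, and the mono-culture array met 10 of 10.

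Before the data were examined, 27 gene lists with 520 entries were fixed. They cover macrophage, T cell, adult T-cell leukemia and regulatory T cell, B cell, NK and cytotoxic, and other blood cell markers, type I and gamma interferon responses, MHC class I and II, cytokines, chemokines and their receptors, NF-kB, STAT3 and STAT5, and p53 targets, immediate early genes, cell cycle, apoptosis, hypoxia, cholesterol synthesis, the ATF4, heat shock and oxidative stress responses, immune checkpoints, adhesion, and housekeeping genes. The median log2 difference of a list's measured members was set against 10000 random lists of the same size, matched on mean signal in 20 bins. A list stood apart where its percentile was at or under 2.5 or at or over 97.5, which describes these 2 arrays only. The rule for named genes, fixed at the same time, took the 12 genes per direction with the largest difference among those well above background on both arrays whose probes all differed 2-fold the same way. It then took the 5 per direction with the largest lower bound, up to 4 members of each list with 2-fold differences, and a few always named (CD14, CD163, CD68, LYZ, CD4, CD3E, IL2RA, CCR4, MKI67, IL10 and CD274). Names that are identifiers only were left out of the 12 and the 5. These begin with LOC, LINC, ENST, XLOC, lnc or lincRNA, or are open reading frame names. LYZ is not analysed here, and a few genes that the rule names are not reported here. Other members of the lists are named as examples chosen after their values were seen.

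The alternatives fixed in advance were quantile normalization, 50th percentile scaling, cyclic loess, normexp background correction with an offset of 50, the deposited table, 2 other filters on dim probes, the mean of a gene's probes, thresholds of 1.5-fold and 3-fold or by scanner error, random lists without matching, and lists without shared genes. Chosen after seeing the data were scaling over detected probes, bounds for dim genes and a lowess correction for probe GC content. R 4.3.3 with limma 3.58.1 gave the normalizations, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 the rest. The procedure was tested on simulated data drawn from the real means with the scanner errors for these 16780 genes. Of 40 genes changed 3-fold, 38 passed the 2-fold threshold in the right direction, as did 40 of 40 changed 4-fold, 19 of 40 changed 2-fold and 0 of 40 changed 1.5-fold. Of 16580 unchanged genes, 241 passed it by scanner error alone (1.45%). Variation between cultures, RNA preparations and labellings was not simulated, so this share is no false rate for the comparison. The list step was tested on the real differences instead. Of 200 lists of 15 genes drawn at random from them, 12 stood apart with no shift and 197 with an added log2 shift of 0.5. Genes drawn at random stand apart about as often as the percentile bounds set. The 12 are therefore no error rate for lists of genes that vary together.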

Results

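ATN-1 cells were profiled once in mono-culture and once after 3 weeks with monocyte-derived macrophages that were then removed with CD14 beads, 1 array each. The comparison asks how the transcriptome of the leukemia cells differs after growth beside macrophages, a cell type of the lymphoma's surroundings. After filtering, 16780 genes had a value. The arrays correlated across these genes (Pearson r = 0.97, Spearman correlation 0.98), where genes are not independent replicates. There are no replicates, so every value below is a difference between these 2 arrays.

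Among 16780 genes, 828 were at least 2-fold higher after co-culture (4.93%) and 690 at least 2-fold lower (4.11%). Of the 13570 named from the RefSeq table, 619 were at least 2-fold higher and 422 lower. Over all 16780 genes the median log2 difference was −0.015, and the 5th and 95th percentiles were −0.89 and 0.99. Many genes past 2-fold were dim on 1 array, and with such genes counted by their bound 645 were at least 2-fold higher and 441 lower. List counts below use the bounds. Over genes well above background on both arrays, 411 were at least 2-fold higher and 268 lower. With normexp background correction, which shrinks dim differences, the counts were 277 and 116, so that higher genes made up 70.5% of them, against 54.5% in the main setting. With 50th percentile scaling 757 were higher and 802 lower, or 48.6% higher. Of 168 genes with several probes and a 2-fold difference, 105 had all probes 2-fold the same way and 20 had a probe that differed in the other direction.

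The genes ranked here were well above background on both arrays, had all probes 2-fold the same way, and had more than an identifier as name. Among them the largest difference was that of ITLN1, which encodes the lectin intelectin 1. Its signal was 59.4 in mono-culture and 2367 after co-culture, 45.8-fold higher. HSD11B1, which encodes the enzyme that converts cortisone to cortisol, was 37.6-fold higher (143 and 4672). Next came PLEKHG3 (28.2-fold) and HBZ, here the human hemoglobin zeta gene rather than the viral gene of the same symbol (22.6-fold, with its 3 probes between 3.57 and 6.45 on the log2 scale). ELF3, an epithelial ETS transcription factor, was 20.2-fold higher, and AIRE, the regulator of self-antigen expression in the thymus, 19.5-fold. The remaining genes of this set were CCNA1 (cyclin A1, 17.3-fold), the channel gene CALHM3 (15.6-fold), FGFBP1 (fibroblast growth factor binding protein, 15.3-fold), JAKMIP3 (15.2-fold), ECM1 (extracellular matrix protein, 15.1-fold) and the cytotoxic granule gene NKG7 (13.7-fold). The scanner error of these log2 differences lay between 0.21 for HSD11B1 and 0.35 for JAKMIP3. With normexp these folds were smaller and their order changed. HSD11B1 was then 26.9-fold, ITLN1 22.8-fold, ELF3 13.2-fold, AIRE 11.6-fold, PLEKHG3 10.5-fold and HBZ 9.88-fold higher, and the other genes lay between 4.42-fold for JAKMIP3 and 7.99-fold for FGFBP1. In build hg19, the ITLN1 probe lies on chromosome 1 from 160846366 to 160846425, the HSD11B1 probe on chromosome 1 from 209907901 to 209907960, and the AIRE probe on chromosome 21 from 45717745 to 45717804.

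In the other direction, the keratin gene KRT19 was 14.1-fold lower, at 698 in mono-culture and 43.2 after co-culture. The actin adaptor gene BAIAP2 was 8.88-fold lower (3 probes, −4.02 to −1.18 on the log2 scale). TNFRSF11A, which encodes the receptor RANK, was 8.70-fold lower, and TERT, the catalytic subunit of telomerase, 6.15-fold (946 and 134). CD7, a T cell surface antigen, was 5.62-fold lower. The other genes were DOK7 (7.73-fold), ARHGEF16 (7.52-fold), CACFD1 (6.77-fold), TBC1D16 (6.71-fold), GLIS1 (6.57-fold), FAM30A (6.37-fold) and FBLN2 (fibulin 2, 5.31-fold). With normexp KRT19 was at −2.59 on the log2 scale. BAIAP2 was then 5.55-fold, TERT 4.56-fold, TNFRSF11A 3.79-fold and CD7 2.22-fold lower, and the other 7 genes lay between 2.65-fold for TBC1D16 and 5.07-fold for GLIS1. In hg19 the KRT19 probe lies on chromosome 17 from 39679918 to 39679977 and the TERT probe on chromosome 5 from 1253305 to 1253364. The scanner error was between 0.21 for FBLN2 and 0.32 for CD7.

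Genes not well above background on 1 array are given by their bound. BIK, a pro-apoptotic BH3-only gene, was at least 24.9-fold higher after co-culture. FCRLB was at least 13.3-fold, PSCA 12.8-fold, the myeloid Src family kinase gene FGR 9.43-fold and LRRC31 8.84-fold higher. COL6A2, a collagen VI chain, was at least 22.4-fold lower, followed by KIAA0513 (16.9-fold), AATK (12.7-fold), RAB17 (10.6-fold) and RADIL (9.91-fold). These bounds hold for the main background setting. With normexp BIK was 6.69-fold and the other 4 between 2.91-fold (LRRC31) and 3.92-fold (FCRLB) higher, while COL6A2 was 7.64-fold and the others between 3.08-fold (RADIL) and 4.84-fold (KIAA0513) lower.

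**Figure D1:**
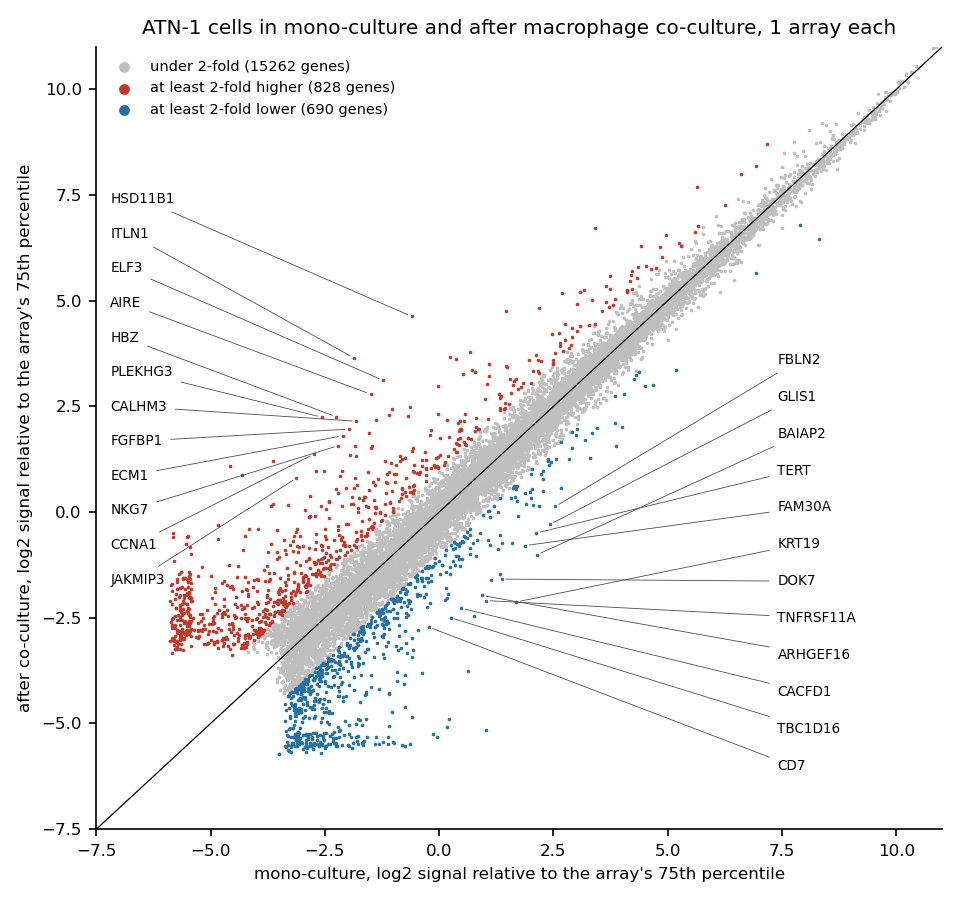
Each point is 1 of 16780 genes, with its log2 signal in mono-culture on the x axis and after co-culture on the y axis, both relative to the array's 75th percentile, and the line marks equal values. The 828 genes at least 2-fold higher (red) and 690 at least 2-fold lower (blue) include vertical and horizontal bands of genes dim on 1 array, while the 24 labelled genes were well above background on both.

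Macrophage markers were higher after co-culture. Of 20 measured markers, 11 were at least 2-fold higher and none 2-fold lower, with a median log2 difference of 1.80 (percentile 100 among random lists). With normexp background correction the median was 0.65, still at percentile 100, with APOE at 2.51, APOC1 at 1.11 and CD14 2.14-fold higher, and ITGAX (0.80) and C1QB (0.69) were under 2-fold. APOE, a lipid carrier, was 138 in mono-culture and 1054 after co-culture (log2 difference 3.13). CD14, the target of the beads, was 21.1 and 94.6 (2.36), and the lysosomal marker CD68 was 113 and 351 (1.83). Several markers were not well above background in mono-culture, and were higher by at least 3.32-fold (APOC1), 3.31-fold (ITGAX) and 2.58-fold (C1QB). With such members at their bounds the list's median was 1.32, and over the 13 members well above background on both arrays it was 1.27, with 7 of them at least 2-fold higher. CSF1R, the receptor of macrophage colony-stimulating factor, differed by 0.34, and the protease gene LGMN by −0.54. Another 13 markers, among them CD163, C1QA, MRC1 and MSR1, were not well above background on either array.

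Genes of NK cells and cytotoxic lymphocytes were higher together. Of 7 measured, 6 were at least 2-fold higher and none lower, with a median of 2.25 (percentile 100). Besides NKG7, they included GZMA and GZMB, which encode granule proteases (2.48 and 2.17), PRF1, which encodes perforin (2.34), and GNLY, which encodes granulysin (2.25). PRF1 was 213 in mono-culture and 938 after co-culture. The NK markers KLRD1, KLRF1, KLRB1, CST7 and GZMK were not well above background on either array. With normexp the median was 1.47, with GZMA at 1.16 and GNLY at 1.06. On the same array the macrophage markers above were higher.

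T cell identity genes had a median of −0.31 (percentile 0.20, mean −0.46), with 3 of 15 at least 2-fold lower and none 2-fold higher. Besides CD7 these were CD3D (−1.17) and CD3G (−1.16), genes of the CD3 complex of the T cell receptor, which with normexp were at −0.63 and −0.28. CD3E was well above background in mono-culture only and at least 1.14-fold lower. CD2 (0.02) and CD4 (−0.08) had similar signals on both arrays, and the adaptor gene LAT was at 0.70. The list's median was −0.12 (percentile 7.62) with normexp background correction and −0.03 (percentile 21.7) without the filter on dim probes, so that it no longer stood apart in either. Macrophage markers had a median of 1.80 between the same arrays, and NK and cytotoxic markers a median of 2.25. Markers of adult T-cell leukemia and regulatory T cells had a median of 0.18 and a mean of −0.12, opposite in sign (percentile 99.4), with 1 of 17 members at least 2-fold higher and 1 lower. The costimulatory receptor gene ICOS was at least 4.42-fold lower (−0.94 with normexp), TNFRSF9, which encodes 4-1BB, was at 1.32, CCR4 at −0.92 and IL2RA, the alpha chain of the interleukin-2 receptor, at 0.19.

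Other blood cell markers were measured for few genes. Among 5 B cell genes, CD22 was at least 3.21-fold (−0.60 with normexp) and TCL1A at least 1.38-fold lower, while CD79A was at 0.28. That list's median of 0.08 and mean of −0.83 differed in sign, and it did not stand apart (percentile 68.4). Of 4 measured platelet, granulocyte and erythroid markers, 1 was at least 2-fold higher, the granulocyte and monocyte gene S100A12 at 2.74, or 1.41 with normexp (median 0.67, percentile 98.8). Without the filter on dim probes that list's median was 0.24 (percentile 92.1). Between the same arrays CD14 was at 2.36 and macrophage markers had a median of 1.80.

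**Figure D2:**
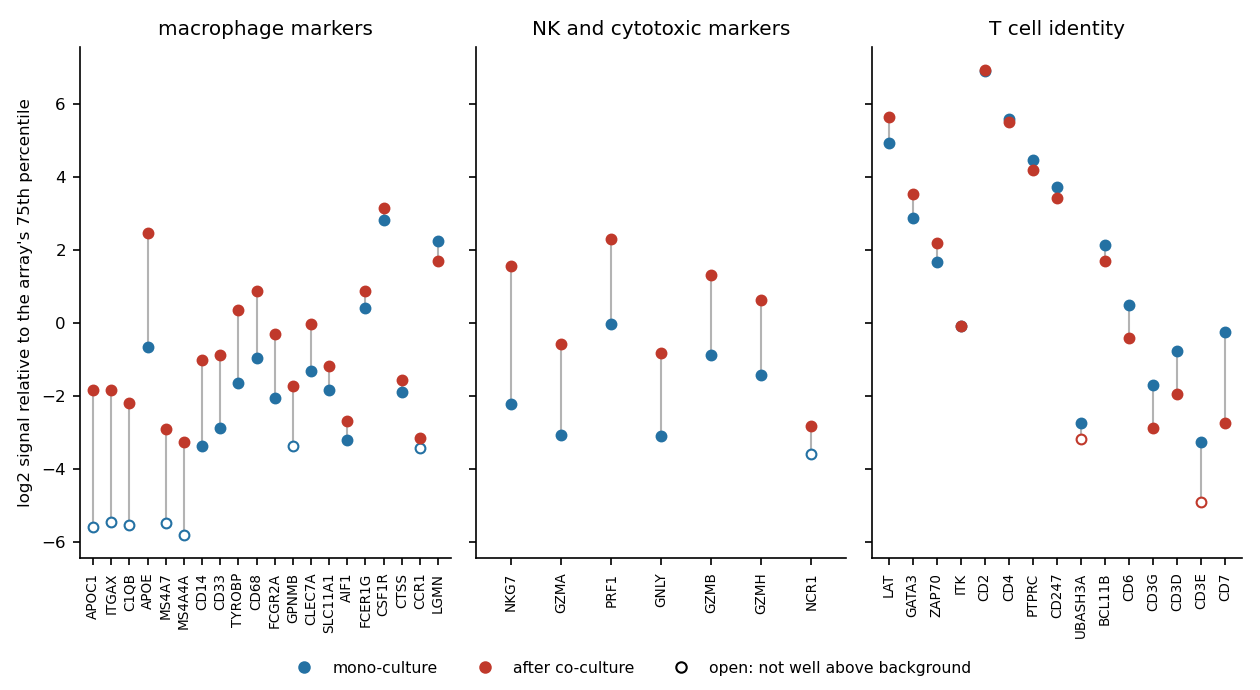
Each gene's log2 signal relative to the array's 75th percentile (y axis) is shown in mono-culture (blue) and after co-culture (red), for the measured macrophage (20), NK and cytotoxic (7) and T cell identity (15) genes on the x axes, with open circles where the probe was not well above background. APOE, CD14, NKG7 and PRF1 were higher after co-culture, and CD7, CD3D and CD3G lower.

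Type I interferon response genes were higher as a group. Of 24 measured, 10 were at least 2-fold higher and none lower, with a median of 0.81 (percentile 100). The antiviral gene MX1 was at 2.17 (1.09 with normexp) and IFI27 at 2.09. IFIT2 was 3.29-fold higher against its own mono-culture signal of 21.9, which was not well above background. IFI44L was at least 2.15-fold higher, and with normexp IFIT2 and IFI44L were at 0.69 and 0.75. ISG15 was at −0.15 and BST2 at −0.14. Interferon gamma response genes had a median of 0.45 (percentile 99.99), with 2 of 12 at least 2-fold higher, the chemokine gene CXCL10 at 2.80 (1.68 with normexp) and WARS1, a tryptophanyl-tRNA synthetase, at 1.69. Without the filter on dim probes that median was 0.18 (percentile 96.3). CD14 was at 2.36 on the same array, where 11 of 20 macrophage markers were at least 2-fold higher.

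MHC class II genes had log2 differences below 0 in 10 of 10 members, and none reached 2-fold. The median over 10 genes was −0.57 (percentile 0), from −0.80 for CIITA, the class II transactivator, to −0.06 for CD74, the invariant chain, which is within the scanner error of about 0.20, with HLA-DRA at −0.51 and HLA-DQB1 at −0.78. MHC class I genes had a median of −0.00 and a mean of 0.06 over 12 genes, and the list did not stand apart (percentile 72.2). B2M, the shared light chain, was at 0.60.

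Chemokine genes had a median of 0.37 (percentile 99.7), with 3 of 9 measured at least 2-fold higher and none lower. Besides CXCL10, these were CCL3 (1.54) and CCL4 (1.31), while CCL5 was 3490 in mono-culture and 1829 after co-culture (−0.73). On the same array macrophage markers had a median of 1.80. Receptors did not stand apart (median −0.09, mean 0.07, percentile 21.7). CXCR3, the receptor of CXCL10, was 282 and 2313 (3.24, with its other probe at 1.28), and the skin-homing receptor gene CCR10 was at −1.29. None of the 12 measured cytokine genes reached 2-fold. Their median was 0.21 (percentile 98.5), with TNF at 0.58 and LTB at 0.56, and IL10 was not well above background on either array. The list no longer stood apart without the filter on dim probes (0.17, percentile 67.0) or without genes shared between lists (0.19, percentile 96.9).

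Among signalling targets, STAT3 and STAT5 genes had a median of 0.63 (percentile 100), with 4 of 16 at least 2-fold higher and none lower. These were FURIN (1.53), the cyclin genes CCND3 (1.32) and CCND2 (1.03), and CISH (1.15), a feedback inhibitor of cytokine signalling, with CCND2 at 0.91 with normexp. MYC was at −0.50. Immediate early and T cell activation genes had a median of 0.67 (percentile 100), with 3 of 12 at least 2-fold higher and none 2-fold lower. Of the 12, 9 were above 0 and 3 below it, NR4A3 (−0.73), DUSP2 (−0.54) and JUNB (−0.36). KLF2, a transcription factor of resting and recirculating T cells, was 2291 in mono-culture and 19758 after co-culture (3.31), and EGR1 (1.25) and DUSP6 (1.35), targets of the ERK pathway, were also past 2-fold, but with normexp at 0.68 and 0.55. The KLF2 probe lies on chromosome 19 of hg19. On the same array macrophage markers had a median of 1.80 and CD14 was at 2.36. NF-kB targets did not stand apart (median 0.01, mean 0.23, percentile 58.3, and a median of −0.08 with 50th percentile scaling). Of 18, 2 were at least 2-fold higher, TNFAIP3 (1.49) and TNFAIP2 (at least 2.21-fold, and 0.51 with normexp).

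Cell cycle genes had a median of 0.18 over 25 genes (percentile 99.97), and none reached 2-fold. Of these, 16 were above 0 and 9 below it, from TOP2A at 0.58 to MCM4 at −0.44, with MKI67 at 0.35. p53 targets had a median of 0.26 (percentile 99.6), with 2 of 14 at least 2-fold higher, the cell cycle inhibitor gene CDKN1A and GADD45A (1.30). CDKN1A was 4.84-fold higher against its own mono-culture signal of 23.8, which was not well above background. With normexp it was at 0.97. Apoptosis regulators had a median of 0.31 (percentile 99.99). Of 20, 2 were at least 2-fold higher, among them CFLAR, an inhibitor of caspase 8 (1.04, with 4 probes from −0.01 to 1.04, 0.94 with normexp and 0.66 as the mean of its probes).

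The medians of 2 metabolic lists stood apart toward lower values. Of 18 cholesterol synthesis genes, 17 were below 0 and none reached 2-fold, with a median of −0.38 (percentile 0). SQLE, which encodes squalene epoxidase, was at −0.63, INSIG1 at −0.63 and LSS, which encodes lanosterol synthase, at −0.62. Hypoxia and glycolysis genes had a median of −0.20 (percentile 0.31), with 1 of 21 at least 2-fold higher and 2 lower. PFKFB4 (−1.69) and the carbonic anhydrase gene CA9 (−1.16) were lower. NDRG1 was at 1.69 and the glucose transporter gene SLC2A3 at least 1.90-fold higher. ATF4 and unfolded protein response genes (median −0.01, mean 0.02, percentile 51.8), heat shock genes (−0.14, percentile 7.19) and oxidative stress genes (median 0.03, mean −0.08, percentile 75.7, and a median of −0.05 with 50th percentile scaling) did not stand apart. Members past 2-fold included DDIT4 (1.26) and HMOX1 (−1.16, and −0.33 with normexp).

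Immune checkpoint genes went both ways. Of 11 measured, 5 were at least 2-fold higher and 1 lower, with a median of 0.33 (percentile 99.4). HAVCR2, which encodes TIM-3, was at 1.48. The ligand genes CD276 and CD274, which encodes PD-L1, were at least 2.98-fold and 2.09-fold higher, while PDCD1, which encodes PD-1, was 163 in mono-culture and 48.4 after co-culture (−1.55). With normexp PDCD1 (−0.85), CD276 (0.59) and CD274 (0.50) were under 2-fold. Macrophage markers on the same array had a median of 1.80, with CD14 at 2.36. Adhesion and migration genes had a median of 0.25 (percentile 99.9), with 2 of 16 at least 2-fold higher, the integrin genes ITGB7 (1.41), whose product pairs with alpha 4 in gut homing, and ITGA5 (1.18, and 0.73 with normexp). With the mean of a gene's probes that list had a median of 0.14 (percentile 97.4). Housekeeping genes had a median of −0.04 and a mean of 0.02 over 16 genes, from −0.33 to 0.31 (percentile 45.2). In all, 19 of the 27 lists stood apart, 15 toward higher and 4 toward lower values.

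**Figure D3:**
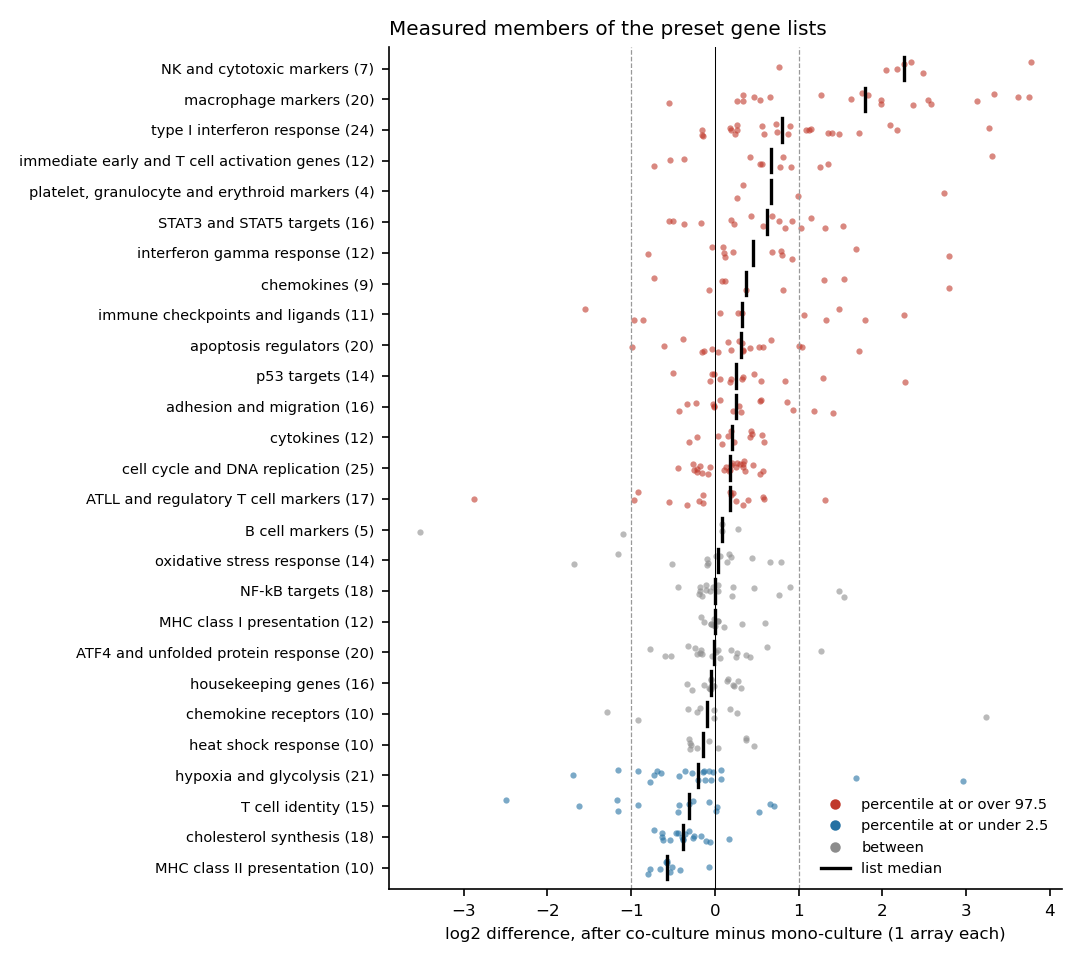
Each point is the log2 difference (x axis, after co-culture minus mono-culture, 1 array each) of 1 measured member of a preset list (y axis, number of members in brackets), the black bars are list medians, and the dashed lines mark 2-fold. NK and cytotoxic markers (median 2.25) and macrophage markers (1.80) lie farthest to the right, and MHC class II (−0.57) and cholesterol synthesis genes (−0.38) farthest to the left.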

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

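Probes without a gene name were not used in the comparisons above. Of 739 such probes well above background on at least 1 array, 28 were at least 2-fold brighter after co-culture (3.79%) and 23 at least 2-fold dimmer. Of the 28, 11 were well above background on both arrays. They drew attention as signal in data that no comparison used, and with no mapping of these probes to genes here, no explanation was tested.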

How the results depend on the processing

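No direction of a named gene or of a list standing apart was reversed in any alternative run. Across named genes, 768 values kept their side of 2-fold, 26 dropped under it, mostly with normexp, and 1 passed it (CCR4). For the counts, lists and correlation, 365 values counted as unchanged, 7 list medians no longer stood apart and 23 values moved. A count was unchanged if within 1.5 times its main value. A list that stood apart was unchanged if it still did so in the same direction, whatever its size. With normexp the macrophage median was thus unchanged at 0.65, against 1.80 in the main setting. The NK and cytotoxic median was so at 1.47, against 2.25. The cause was not tested unless the setting itself shows it. With 50th percentile scaling, the lists for MHC class I (−0.089), NF-kB (−0.082), ATF4 (−0.096), heat shock (−0.23), oxidative stress (−0.054) and housekeeping genes (−0.13) moved, each by the constant between the scalings, and none stood apart. Normexp, which shrinks dim differences, gave 277 genes higher and 116 lower (70.5% higher, against 54.5%), a correlation of 0.988 and a T cell identity median of −0.12. Genes well above background on both arrays numbered 411 higher and 268 lower, with r = 0.984. With no filter, where more dim genes enter, 2325 were higher and 1407 lower, the median of all genes was 0.16 and r was 0.984. The T cell identity (−0.028), platelet, granulocyte and erythroid (0.24), interferon gamma (0.18) and cytokine (0.17) medians then no longer stood apart, and that of chemokine receptors was 0.13. The mean of a gene's probes put adhesion at 0.14, and leaving out shared genes put cytokines at 0.19, both just inside the random range. A 1.5-fold threshold gave 1573 higher and 1624 lower, and a 3-fold one 468 and 327. Of the alternatives chosen after seeing the data, counting dim genes by their bound gave 645 higher and 441 lower, and the macrophage median at bounds was 1.32. Other scalings kept both counts within 1.5 times, with 757 to 843 higher and 680 to 802 lower, but 50th percentile scaling turned the balance, with 757 higher and 802 lower (48.6% higher). No paired analysis was possible because each group holds 1 array. Signal near background limits dim genes, and those whose probes were all not well above background on 1 array are given by their bounds.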

Other observations

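The tests of probes near background and the correction for probe GC content were chosen after the data were seen. The additional gene lists were drawn up after the comparisons above and before the values of their members were looked at. Of 38 abundant macrophage transcripts outside the preset lists, 17 were well above background on both arrays. Of these, 12 were above 0 and 5 below it, 6 were at least 2-fold higher and none lower, and the median was 0.57. The genes named here were chosen after their values were seen. S100A8, which encodes a calcium-binding protein of granulocytes and monocytes, was 597.5 in mono-culture and 5104 after co-culture (log2 difference 3.30), and its partner S100A9 was 40.8 and 227 (2.68). The actin-capping gene CAPG was 984 and 5352 (2.65), and the inhibitory receptor gene LILRB4 was 448 and 1540 (1.98). CTSL was at −0.18, NPL at −0.10, LIPA at −0.03 and IFI30 at 0.26. From a list of glucocorticoid targets, ANXA1, which encodes annexin A1, was 254 and 2414 (3.45). In T helper 1 genes, BHLHE40 was at 1.62, STAT4 at 1.09 and TBX21, the T-bet gene, at 1.03, whereas TNFSF14 was at −1.05. IL2RB, the beta chain of the interleukin-2 receptor, was 9843 and 14200 (0.73), and the lipogenic regulator gene SREBF1 was at 1.00.

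Macrophages left after the CD14 bead step are a candidate source of the higher macrophage markers. Of the 38 abundant macrophage transcripts, 18 were already well above background in mono-culture. Of the other 20, 4 were so after co-culture (20%, exact 95% interval 5.73% to 43.7%), namely FCGR2B (signal 65.8), SPP1 (63.7), ACP5 (54.9) and CHI3L1 (26.9), against 3.06% of all 18117 genes dim in mono-culture. Carry-over was taken beforehand to need at least 50% and its absence at most 25%, a bound that 20% met. The interval was not part of that rule, and it treats genes of 1 array as independent draws. It spans the 25% bound and lies above the 3.06% of all genes, so a small share of macrophages stays open. Dim probes do not settle it either, since the 13 markers well above background on both arrays had a median of 1.27, with 0.89 to 1.63 from scanner error alone. Macrophage RNA and a response of the ATN-1 cells themselves cannot be told apart for these markers, and the biological difference between the cultures stays open as untested.

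NK cells or cytotoxic T cells carried over with the macrophages might likewise raise the NK and cytotoxic markers. Of 22 further NK cell transcripts, 11 were dim in mono-culture, and 1 of these was well above background after co-culture, HOPX (9.09%, exact 95% interval 0.23% to 41.3%, against 3.06% of all genes), too few genes to exclude it. Of the 22, the 10 well above background on both arrays had a median of 0.34, with 5 above 0 and 5 below it. At least 2-fold higher were 3 and none lower. Among those below 0 were SPON2 at −0.85, CD8A at −0.14 and CD8B at −0.08. The CD14 beads would not remove such cells. For dim probes as the source, the 6 members whose brightest probe was well above background on both arrays had a median of 2.30 (2.06 to 2.60 from scanner error). The other member, NCR1, had its brightest probe not well above background in mono-culture and is left out of that median. Because only NCR1 was left out, that median could hardly differ from the list's own and does not decide the question. In mono-culture GNLY (25.8) and GZMA (26.1) lay near the lowest signal well above background (18.6). With normexp, which shrinks dim differences, the list's median was 1.47, still at percentile 100, with GZMA at 1.16 and GNLY at 1.06. Signal near background may therefore add to the size of these differences. Expression of the NK and cytotoxic genes by ATN-1 cells after co-culture stays open, untested, beside a small number of other lymphocytes.

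Technical trends were weighed for the 19 lists that stood apart. After a lowess correction for probe GC content, 19 of 19 still did, and the fitted shift lay between −0.13 and 0.02. After cyclic loess, which removes a trend of the difference with signal, it was again 19 of 19. The random lists were matched on mean signal, so a smooth trend would move a list and its random lists alike. Cyclic loess is therefore no separate check here. The trend with GC content does not account for the set of lists. Both arrays shared a slide and a scan, and what the lack of replicate cultures adds was not tested, so part of the list shifts could reflect culture-to-culture variation.

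A wider T helper 1 program is a hypothesis for CXCR3, granzymes and perforin being higher together. The list of 12 further T helper 1 genes, 4 of which also stand in the NK list, had 8 measured, with a median of 0.82 and a percentile of 99.99. Of these, 4 were at least 2-fold higher and 1 lower. That percentile met the bound set beforehand for the hypothesis. Several of these genes are also expressed in NK cells, so it does not separate the sources. IFNG, the interferon gamma gene of the preset cytokine list, was not well above background on either array.

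For the cholesterol genes, higher LXR activity may be one hypothesis, because APOE and APOC1 are LXR targets. The other 8 measured LXR targets had a median of 0.21 (mean 0.24) at a percentile of 97.3, just under the upper bound set beforehand, with SREBF1 at 1.00 but ABCA1 at −0.05 and PLTP at −0.49. That leaves it undecided. For HSD11B1, higher glucocorticoid signalling was the hypothesis. The 7 measured targets had a median of −0.02 and a mean of 0.56 at a percentile of 40.4, with FKBP5 at −0.14 and PER1 at −0.02 beside TSC22D3 at 0.64 and ANXA1 at 3.45. A percentile of at most 75 was set beforehand to count against the hypothesis, and by that rule this one did. Of the 7 members, 3 were above 0, so the list does not exclude the hypothesis.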
